A study of Cucumis sativus with 4 samples.

How the data were processed

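RNA sequencing was done on young fruits of the CsFUL1 overexpression line OX-29 and of WT, 2 libraries each. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, libraries were made with the NEBNext Ultra kit and paired-end reads were produced on an Illumina HiSeq instrument. The design text calls the lines near-isogenic, while the labels' protocols describe a transformed line. The submitters' processing notes name TopHat, a spliced aligner, and HTSeq, a read counter. Their versions and settings, the genome build and the annotation are not given in the sources used here. Whether counting used strand is not given, so reads of overlapping or antisense genes cannot be separated, and how reads shared by near-identical gene copies were counted is not given.

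The deposited values are CPM, 1 column per library, for 17180 genes. Each column sums to 1000000 over these genes, so the authors computed the deposited CPM after genes with low values had been left out: each listed gene has at least 0.897 CPM in 2 or more libraries. This scaling makes a gene's CPM depend on what the other genes take, and this affects the balance of rises and falls. Every value is a whole multiple of its column's smallest non-zero value (100% within 0.001 reads). Whole reads were therefore recovered, and they give totals of 16326412 to 19824797 reads per library. These totals cover listed genes only. Reads are not molecules, since no molecular identifiers were used, so counting intervals and the 3-count limits cover counting error only. The number of per-sample columns left out was 0.

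Columns were assigned to samples by their names, which equal the sample titles. None of the 17180 identifiers matched the RefSeq gene table that was at hand (0 matches among 23999 genes, by gene identifier, locus tag, symbol, synonym or accession). For this reason the 27 gene lists fixed before the data were examined, which were to be formed from gene descriptions, could not be formed, including the marker lists of phloem, xylem, pollen, ovule and epidermis. The same holds for the row of CsFUL1. Checks on gene length or GC content were not made, and no genomic coordinates are given. In such a case the rule for named genes, also fixed before the data were examined, allows at most 2 identifiers that rose and 2 that fell. They are the largest rises and falls in log2 fold change among genes that passed the threshold and whose OX-29 and WT libraries did not overlap.

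The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on log2(CPM + 0.5), with the line as the only term and Benjamini-Hochberg adjustment over the 16982 genes with a mean of at least 1 CPM over the 4 libraries. The 198 others were not tested. The threshold was an adjusted p under 0.05. With 2 libraries per line, p-values measure the spread between these libraries. The labels call them biological replicates but do not say how many fruits or plants each one holds. The replicate numbers 1 and 2 are shared by the lines, but no label says that they pair samples, so the main model has no block.

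Alternatives were other pseudocounts, no filter or a stricter one (mean of at least 5 CPM), median-of-ratios scaling, quantile normalization, eBayes without trend or with robust variance, the replicate number as a block, each library left out in turn, stricter thresholds, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. Alternatives chosen after seeing the data were edgeR without TMM factors, rescaling without the 100 most abundant genes and thinning of reads to equal totals, and median-of-ratios scaling of the fold sizes and of the calls by chromosome. The near-silent groups, the lists of the 100 most abundant genes, the abundance classes and the neighbour statistics were likewise chosen after the file had been seen. Neighbours are successive tested genes of one chromosome in identifier order, with unplaced genes left out.

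The limma step was tested on simulated counts for OX-29 against WT, drawn from the mean of all libraries with the estimated dispersions, with 200 changed genes of at least 10 CPM among 16912 genes tested. It recovered 96% of 4-fold rises, 92% of 4-fold falls, 12% of 2-fold rises and 10% of 2-fold falls, and 8 unchanged genes were called, 7.08% of the calls. In that simulation few genes changed, which makes the adjustment stricter than in the data. It also gave both lines the same dispersion for a gene and held as many rises as falls. In the data the common dispersion was 0.101 in WT and 0.0383 in OX-29, and falls outnumbered rises. The share of false calls may therefore differ in the data.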

Results

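Messenger RNA was measured in young cucumber fruits (Cucumis sativus) taken 4 days before anthesis, when the fruit is still an unopened flower's ovary. OX-29 is a line of inbred R1407 that carries CsFUL1, a MADS-box transcription factor gene related to FRUITFULL, under the strong cauliflower mosaic virus 35S promoter, and its fruits are short. The wild type (WT) is R1407 itself, with long fruits. Each line gave 2 libraries, described as biological replicates. The libraries held 16719990 and 16326412 gene-assigned reads in OX-29 replicates 1 and 2, and 19824797 and 16858940 in WT replicates 1 and 2. Levels are given as CPM, the reads of a gene per 1000000 reads of its library. A single read was worth 0.0504 to 0.0613 CPM, and 0 reads in a library allow a level of up to 0.151 to 0.184 CPM (3 counts), for counting error only. The table lists 17180 genes by identifier, and no table used here pairs these identifiers with gene names. The level of CsFUL1, which would check the line labels, and those of CsSUP and the auxin transporters named by the study's topic are therefore not analysed here.

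The design implies a single comparison, OX-29 against WT, which asks which genes differ between the short fruits of OX-29 and the long fruits of WT. OX-29 was the only transformed line sampled, so traits of that line and effects of CsFUL1 cannot be told apart. The fruit transcriptomes of the lines differed over much of the gene set. Of 16982 genes tested, 6522 were lower and 3155 were higher in OX-29, and 7305 did not pass (limma on log2(CPM + 0.5), Benjamini-Hochberg adjusted p under 0.05). The calls made up 57.0% of the tested genes, and their median absolute log2 fold change was 1.62, against a median standard error of 0.26. The fit assumes the same spread in both lines for a gene, although the common dispersion between replicates was 0.101 in WT and 0.0383 in OX-29. Between lines, the Pearson correlation of log2 values across genes was 0.69 to 0.71. Within a line it was 0.98 for OX-29 and 0.95 for WT. In 81.7% of tested genes the OX-29 libraries did not overlap the WT libraries on the deposited scale. A random order of 2 against 2 would give 33.3% for a single gene. Genes of a library vary together, so the share is no test of chance, and its value after median-of-ratios scaling is not given here. Leaving out OX-29 replicate 1 reduced the calls to 5674, and leaving out OX-29 replicate 2 reduced them to 5873. The remaining OX-29 library is then assumed to vary as the WT libraries do.

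The split between rises and falls depended on how the libraries were scaled. With CPM as deposited, the median gene had a log2 fold change of -0.38, and 32.6% of calls were rises. With median-of-ratios scaling, which moved the median to -0.03, 4627 genes were higher and 4955 were lower, so 48.3% of calls were rises. This scaling applies 1 factor per library. An edgeR quasi-likelihood test on whole reads recovered from the CPM steps, with TMM factors, gave 4470 higher and 5051 lower genes. Directions below are on the deposited scale, with median-of-ratios values given beside the counts of gene groups.

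**Figure D1:**
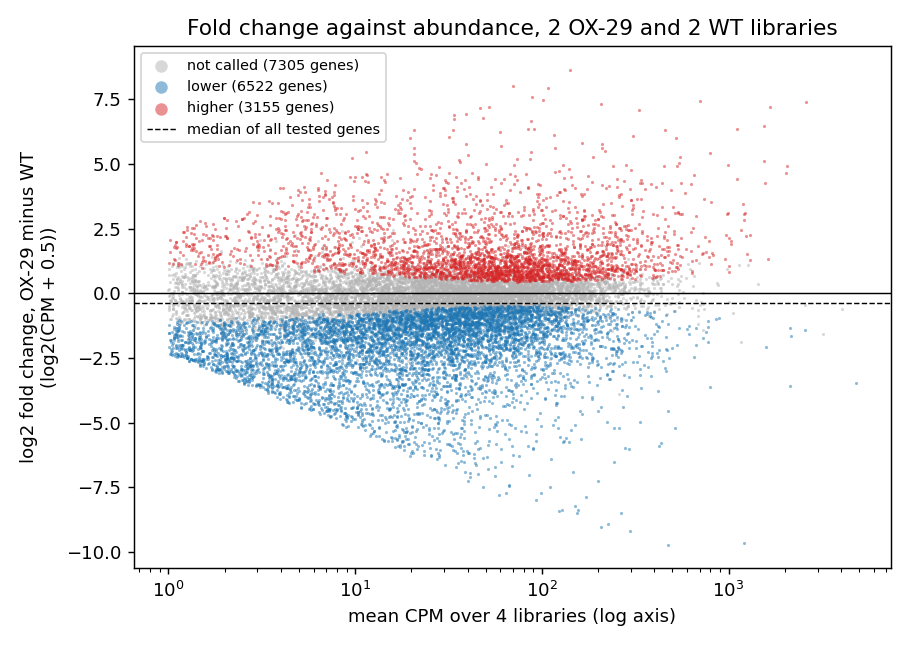
Log2 fold change (OX-29 minus WT, on log2(CPM + 0.5)) of each of 16982 tested genes against its mean CPM over the 4 libraries (log axis). Red points are the 3155 genes higher in OX-29, blue the 6522 lower and grey the 7305 not called, and the dashed line marks the median of -0.38.

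Many of the changes were large. Of the calls, 78.5% were at least 2-fold, with 2155 rises and 5441 falls. At 8-fold or more there were 373 rises and 1289 falls, and at 64-fold or more 30 rises and 74 falls. After median-of-ratios scaling the counts were 3253 rises and 4195 falls at 2-fold, 485 and 1015 at 8-fold, and 34 and 51 at 64-fold. These folds are on the log2(CPM + 0.5) scale, which understates changes of genes with few reads. On this scale Csa3G379740 showed the largest rise, from 0.199 ± 0.138 CPM (SD, n = 2) in WT to 284 ± 88.2 CPM (SD, n = 2) in OX-29. Its log2 fold change was 8.65 ± 0.32 (SE), with a limma adjusted p of 0.000272, and the ratio of pooled reads was 1486 with an exact 95% counting interval of 721 to 3696. Csa5G648730 followed, at 140 ± 45.0 CPM in OX-29 (SD, n = 2) and a log2 fold change of 8.02 ± 0.33 (SE; limma adjusted p = 0.000273). It had 1 read in WT replicate 1 and 0 in WT replicate 2, so the ratio of pooled reads was 5140 with an exact 95% counting interval of 922 to 203047. The order of these 2 genes depended on the scale: with a pseudocount of 0.1 the log2 fold change was 10.12 for Csa5G648730 and 9.94 for Csa3G379740, and with DESeq2 it was 12.69 and 10.90. The largest falls on the log2(CPM + 0.5) scale were in Csa7G067350 and Csa1G604040. Csa7G067350 fell from 946 ± 379 CPM (SD, n = 2) in WT to 0.640 ± 0.482 CPM (SD, n = 2), a log2 fold change of -9.71 ± 0.41 (SE; limma adjusted p = 0.000273). Csa1G604040 fell from 2411 ± 944 CPM (SD, n = 2) to 2.55 ± 1.41 CPM (SD, n = 2), a log2 fold change of -9.65 ± 0.41 (SE; limma adjusted p = 0.000279). The 4 genes were picked among those whose OX-29 and WT libraries do not overlap.

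**Figure D2:**
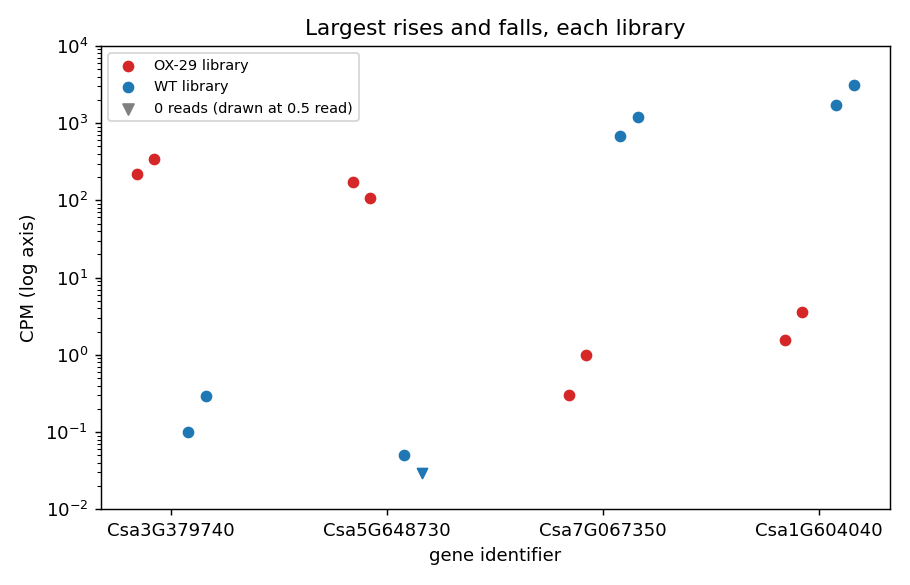
CPM (log axis) of the genes with the largest rises (Csa3G379740, Csa5G648730) and falls (Csa7G067350, Csa1G604040) on the log2(CPM + 0.5) scale, 1 point per library, red for OX-29 and blue for WT. The triangle stands for 0 reads. For each gene the lines are separated by far more than their replicates, as in 284 against 0.199 CPM for Csa3G379740.

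A group of genes was close to silent in one line and expressed in the other. In OX-29, 298 genes lay below 1 CPM in both libraries while both WT libraries held at least 10 CPM. Their median WT level was 28.6 CPM, 23 of them reached a mean of 100 CPM or more in WT, and 5 had 0 reads in both OX-29 libraries. The reverse group, below 1 CPM in both WT libraries and at least 10 CPM in both OX-29 libraries, held 38 genes with a median OX-29 level of 34.2 CPM. Only 1 of these had 0 reads in both WT libraries. After median-of-ratios scaling the groups held 234 and 53 genes. With 1 library left out the reverse group held 48 to 62 genes. Leaving out a library removes a condition, so this count can only stay or rise. Genes with 0 reads were also more numerous in the OX-29 libraries, at 190 and 215 against 23 and 44 in the WT libraries, although WT replicate 2 was about as deep as OX-29 replicate 1.

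The lists of the most abundant genes overlapped little between the 2 lines. The 100 most abundant genes of OX-29 and the 100 of WT shared 19 members. The overlap between replicates of one line is not given here, so this number has no baseline. Of the OX-29 list, 82 genes rose, 3 fell and 15 did not pass, and the list took 14.4% of OX-29 reads and 5.19% of WT reads. Of the WT list, 65 genes fell, 5 rose and 30 did not pass, and it took 11.3% of WT reads and 5.16% of OX-29 reads. The lists were picked from these libraries, so their directions are not independent evidence. After median-of-ratios scaling, 84 of the OX-29 list rose and 51 of the WT list fell. The gene with the most reads in OX-29 stood at 5170 ± 571 CPM (SD, n = 2) there and at 29.9 ± 2.33 CPM (SD, n = 2) in WT, a log2 fold change of 7.41 ± 0.21 (SE; limma adjusted p = 0.00024). The gene with the most reads in WT stood at 8950 ± 7054 CPM (SD, n = 2) in WT and 696 ± 252 CPM (SD, n = 2) in OX-29 (log2 fold change -3.46 ± 0.70 SE; limma adjusted p = 0.00911).

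Falls outnumbered rises among genes of low abundance, and rises outnumbered falls among abundant genes. Of the 2940 genes with a mean of 3 to 10 CPM, 1290 fell and 308 rose, with a median log2 fold change of -0.81. Of the 5552 genes at 30 to 100 CPM, 2013 fell and 1239 rose (median -0.22), but after median-of-ratios scaling 1419 fell and 1851 rose, so the direction of this middle class depended on the scaling. Of the 415 genes at 300 CPM or more, 200 rose and 86 fell (median 0.64). That last class took 27.8% of the reads in OX-29 and 20.1% in WT. Reads were accordingly held by fewer genes in OX-29, where 1267 and 1249 genes made up 50% of the reads, against 1945 and 1789 in WT. Across genes, fold change and mean CPM had a Spearman correlation of 0.23, in which genes are not independent replicates. Median-of-ratios scaling kept the direction of the low and the abundant class, with 1054 falls and 433 rises at 3 to 10 CPM and 61 falls and 231 rises at 300 CPM or more. It gave class medians of -0.47, 0.15 and 1.01 for the same 3 classes. Quantile normalization, which forces all libraries to one distribution of values, changed the correlation to -0.04 and the class medians to 0.14, 0.03 and 0.31.

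**Figure D3:**
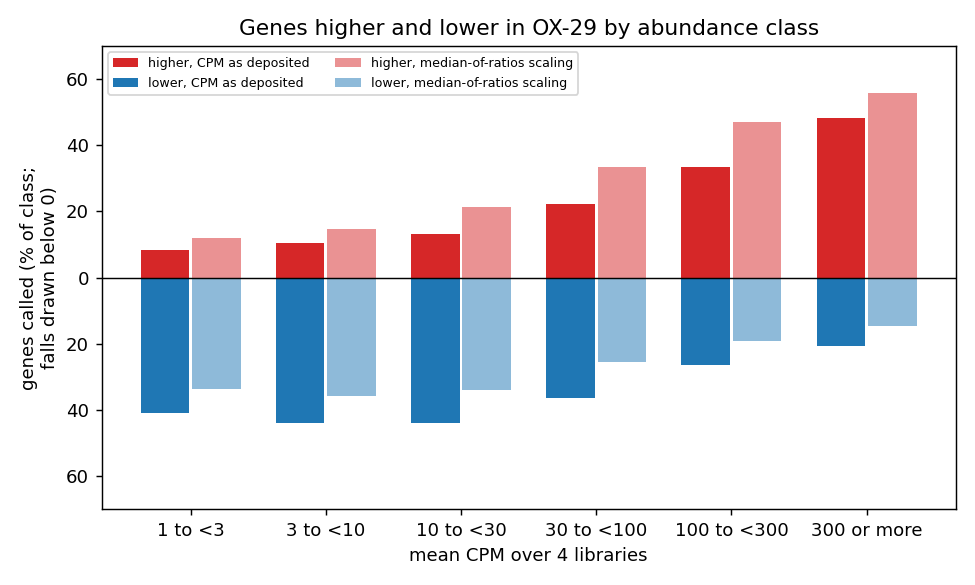
Percentage of genes called higher (red, above 0) and lower (blue, drawn below 0) in OX-29, in 6 classes of mean CPM over the 4 libraries, with CPM as deposited (dark) and after median-of-ratios scaling (light). The share of rises climbed from 8.26% in the lowest class to 48.2% in the highest on the deposited scale, while the share of falls was 41.0% and 20.7%.

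The changed genes were spread over all chromosomes. The digit in each identifier is taken as the chromosome and the number after G as the order along it, as in the cucumber gene naming scheme. Rises made up 17.6% (chromosome 1) to 20.1% (chromosome 6) of tested genes, and falls 37.1% (chromosome 6) to 40.8% (chromosome 1). The calls did not differ detectably between chromosomes (permutation test of the chi-square statistic, 100000 permutations of calls over genes, p = 0.387). After median-of-ratios scaling, rises made up 26.1% (chromosome 1) to 29.3% (chromosome 6) and falls 28.2% (chromosome 7) to 30.9% (chromosome 1), with p = 0.29 in the same permutation test. The test treats genes as exchangeable.

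Neighbouring genes moved alike more often than genes placed at random. Among 16891 pairs of neighbours in identifier order, 3748 were called in the same direction, against 3079 on average after shuffling the genes. Pairs called in opposite directions numbered 2059, against 2417. The correlation of log2 fold changes between neighbours was 0.15, and 0.13 to 0.16 on the single chromosomes (one-sided permutation p = 1e-05 for the correlation and for the same-direction pairs, the smallest that 100000 permutations can give). It dropped to 0.04 at 2 positions apart and to -0.003 at 10. Runs of at least 8 successive genes with the same call numbered 20, against 4.81 on average in 1000 shuffles. All 20 were runs of falls, the longest of 14 genes on chromosome 1. Falls were the commoner call on this scale, which by itself favours runs of falls. Shuffled orders held runs of up to 19 genes. With median-of-ratios scaling there were 8 such runs, 5 of falls and 3 of rises, against 1 on average. The difference between replicates of one line was also alike in neighbours, with correlations of 0.11 in OX-29 and 0.10 in WT.

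**Figure D4:**
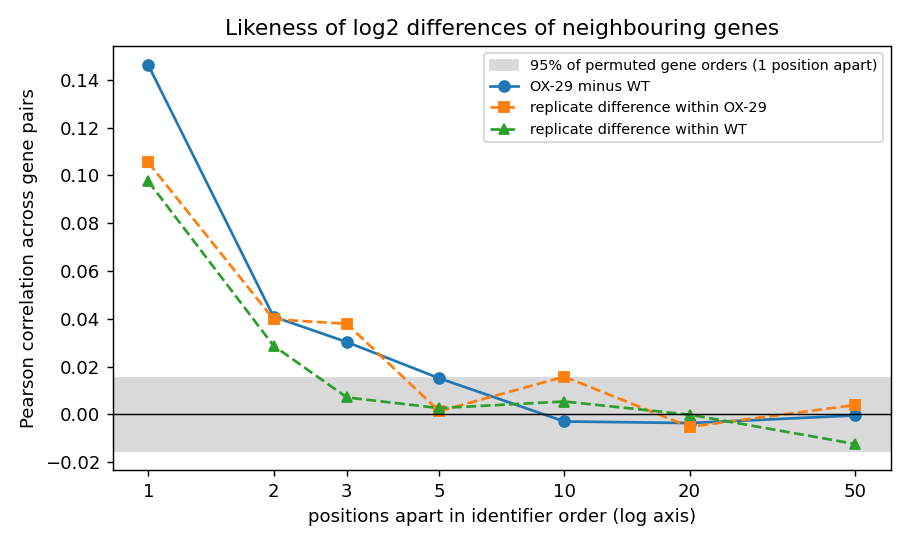
Pearson correlation of log2 differences between genes a given number of positions apart in identifier order (log axis), for OX-29 minus WT (blue circles) and for the difference between replicates within OX-29 (orange squares) and within WT (green triangles). The grey band, computed at 1 position apart, holds 95% of the correlations after shuffling the genes, -0.0153 to 0.0151. The blue line starts at 0.15 and lies within the band from 10 positions on.

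Replicates differed more in WT than in OX-29. The common dispersion between replicates was 0.101 in WT and 0.0383 in OX-29, that is, coefficients of biological variation of 0.318 and 0.196. A chi-square of the read counts over genes came to 91.2 per degree of freedom for the WT pair and 31.7 for the OX-29 pair, so neither pair was one library deposited again. The 3 genes with the most reads in WT replicate 2 stood at 13938, 8056 and 6476 CPM there and at 3962, 2030 and 1511 CPM in WT replicate 1. Those 3 genes took 2.85% of the reads of WT replicate 2, whereas the leading 3 of each other library took 1.25% to 1.33%.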

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

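More genes were called lower than higher under all alternatives run except quantile normalization. Most of these keep the scaling to total reads, so they carry over its excess of falls and are no separate check. Lower and higher genes came nearer balance with median-of-ratios scaling (4955 and 4627), edgeR with TMM factors (5051 and 4470) and DESeq2 (5106 and 4639). The number of genes lower in OX-29 dropped to 4121 with quantile normalization, which gave 4689 higher genes. No pairing by replicate number was seen across genes (the replicate differences of the lines correlated at -0.02). A replicate block gave 9420 calls, 3030 higher and 6390 lower. Leaving out each library in turn gave 5674 to 9229 calls, 1578 to 3139 higher and 4096 to 6313 lower. The low ends came without OX-29 replicate 1, and without OX-29 replicate 2 there were 5873 calls, 1707 higher and 4166 lower, where only the more variable WT pair sets the spread. At an adjusted p under 0.01 there were 6138 calls, 1833 higher and 4305 lower. edgeR gave 9521 calls with TMM factors and 9577 without, and DESeq2 gave 9745. The 4 named genes kept their direction and their side of the threshold in all settings in which they were tested (18 or 19 each), with adjusted p of at most 0.00608. The log2 fold change of Csa5G648730, whose WT level rests on 1 read, ranged from 4.81 with a pseudocount of 5 to 12.69 with DESeq2. That of Csa3G379740, with 2 and 5 reads in the WT libraries, ranged from 5.76 to 10.90 in the same settings. The Spearman correlation of fold with abundance changed sign with quantile normalization (-0.037), which removes differences in the distribution of values by construction, and dropped to 0.149 from 0.231 with a pseudocount of 5. No alternative was run for gene lists or for CsFUL1, as no identifier could be matched to a name. Depth limited statements on near-silent genes to levels above 0.151 to 0.184 CPM.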

Other observations

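Of the tests in this part, those without the 100 most abundant genes, with thinned reads, on the axis between fruits, on the splits and on neighbouring genes were chosen after the data had been seen, and those on repeat libraries and on scaling to total reads (the reading, not the planned median-of-ratios scaling itself) also after their own results had been seen.

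More genes fell than rose in OX-29 (6522 against 3155). A difference in sequencing depth is argued against: with reads thinned to equal totals, 67.4% of the calls were falls, as before thinning. A few abundant genes taking the reads are argued against as the whole cause for the 100 genes of highest mean CPM over all 4 libraries. Without them the median log2 fold change was still -0.33 (from -0.38). That ranking spans both lines, so it cannot tell how much the genes most abundant in OX-29 contribute. The 100 most abundant genes of OX-29 took 14.4% of OX-29 reads and 5.19% of WT reads, and leaving them out was not tested. Scaling to total reads stays open: the falls made up 51.7% of the calls with median-of-ratios scaling, but that scaling centres the folds by construction, and no spike-in was analysed here. Whether most low and middle genes were truly less expressed per cell, or were diluted by a broad class of abundant transcripts, may therefore depend on an outside standard.

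Calls in 57.0% of the tested genes are a wide difference for a comparison described as one transgene in one inbred background. Repeat libraries of one RNA, which would make the spread too small, stay open: the smaller dispersion between replicates was 0.0383 (OX-29), and how much repeat preparations of one RNA vary was not measured here. The hypothesis that the lines differ along an axis that also varies between fruits of one line, such as a small shift in stage, was tested by correlating the replicate difference with the line difference across genes. The larger of these correlations was -0.074 (OX-29, -0.10 to -0.05 on single chromosomes, and 0.01 in WT), so the replicate differences did not follow the line difference. This cannot decide on a shift in stage, since libraries that were pooled or matched in stage need not vary along such an axis. Only 3 splits of the 4 libraries into 2 and 2 exist, too few for a share under 0.05. The real one, 1 of 3, gave 9677 limma calls, and the highest of the others gave 0 (12 and 13 genes at an unadjusted p under 0.05). Each of the others put 1 library of each line in either group, so the line difference widened the spread. Few or no calls could come from them, so the splits are no test of chance. The overexpressed gene stays open, as do a different organ part or stage taken from OX-29 fruits and any difference of growing or handling that follows the lines. All of them follow the lines, as would any other trait of OX-29, so this comparison cannot tell them apart. Without gene names, marker genes of organ part or stage could not be examined either.

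Neighbouring genes changed alike (correlation 0.15). At 20 positions apart the correlation was -0.0036, so folds did not share a direction over long stretches in general. Long chromosome segments that differ between the lines, as lines made by crossing can have, stay open. Genes in such a segment need not all change in the same direction, and a few segments would be lost in an average over all genes. Position-linked variation between libraries of one group is consistent with the data, since replicate differences had a neighbour correlation of 0.11 in OX-29. This likeness could be biological, if neighbours are regulated together, or come from reads shared between tandem copies or overlapping gene models, which was not tested.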
